A study of Mus musculus with 20 samples.

How the data were processed

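Bulk RNA-seq was done on 20 tumours, 5 in each of 4 groups (vehicle, anti-PD-1, letrozole and letrozole + anti-PD-1), per the labels. Per the labels' protocols, RNA was extracted with a Qiagen AllPrep kit and 1 µg of total RNA entered each library, made with a Swift Rapid kit. Per the submitters' processing notes, the tools were STAR 2.7.10a and DESeq2, and the build was GRCm39 (mm39). The version of DESeq2, the read counter, the annotation release, the use of strand and any filter are not given in the sources used here.

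The authors deposited a single table of 127442 Ensembl transcripts by 20 libraries, whose unit is signal: read counts divided by a size factor per library. The division could be undone, since the deposited values of each library are whole multiples of 1 step, and 100% of the values came out as whole reads at a tolerance of 0.001. The recovered size factors ran from 0.472 to 1.46. Among recovered counts of 1 to 20, between 57.9% and 69.6% were even, an excess whose origin is not given in the sources used here. Transcripts of a gene share reads, and 14461 transcripts repeat the values of another. A normalised count is therefore a level and not a number of independent molecules. All 20 columns were used.

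The design fixed before the data were examined assumed a table of genes. Since the deposited table holds transcripts, gene names were taken from GENCODE vM21 (on GRCm38), which named 118889 transcripts (93.3%). The 8553 without a name held 1.79% to 2.76% of reads and were left out of gene tests. Coordinates are not given, since the builds differ. Each of 38996 named genes was represented by its transcript with the most recovered reads over all libraries, after 50 genes with a shared symbol were dropped, and tested genes had a median of 3 transcripts. For 468 tested genes the transcript with the highest median is a different one. Levels of genes that overlap others are uncertain, because the use of strand in counting is not given, and for some this is said beside their values. Of genes named without that remark, Ifng, which is below the filter, shares 20.6% of its exon bases with a gene on the same strand. Foxp3 shares 19.8%, C1s1 19.6%, H2-Q4 19.1%, Rfc4 13.4% and Gpi1 12.3%. Pcdhb21 shares 9.7% with Pcdhb22 on the same strand, Igtp 8.0%, Car9 7.2%, Krt5 5.9%, Lss 5.4%, Rab18 4.7%, Ccdc175 4.6%, Myh2 3.9%, Cdc20 3.0% and Map6d1 2.7%. Gbp2, Cd74, Pdgfra and Slpi share at most 1.0%. Most genes outside the naming rule were not examined for overlap.

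The main test was limma (version 3.58.1) with a trend on log2(value + 1) of the deposited values, for genes with a value of at least 10 in at least 5 libraries (19877 genes). All 20 libraries entered a single fit of group means with 16 residual degrees of freedom, and two-sided p-values were adjusted by Benjamini and Hochberg within each contrast at a threshold of 0.05. Every adjusted p for a gene is from limma unless another tool is named. Contrasts were the 5 pairwise ones, the interaction and, added after seeing the data, the effect of each treatment averaged over both arms. Fold changes are on the log2(value + 1) scale and understate changes of low genes. Values are given as mean ± SD of normalised counts over 5 tumours, and intervals are at 95%. The scaling is the authors', and the median log2 change of all tested genes was 0.03 for letrozole against vehicle.

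A total of 47 lists of pathways and cell type markers and a panel of 17 genes were fixed before the data were examined. The 44 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast. With an estimated correlation no list passed in any contrast. Fry and an exact two-sided permutation test of list means, whose smallest possible p is 0.00794, were run beside it. After adjustment over 44 lists, a list passes the permutation test only if several lists reach that p together. A count of 0 by it is therefore weak evidence against any list. A member was counted as risen or fallen over all genes tested, and separately when adjusted over the list alone.

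The named genes follow a rule fixed before the data were examined. It takes the panel, then up to 8 genes in each direction with the largest change among those past the threshold, above the median level and with no overlap between groups, leaving out predicted genes. For a contrast with fewer than 5 calls it takes the 5 genes with the smallest p in each direction, given as values. It adds up to 4 members of each list that camera called. A few genes that the rule takes are not reported here.

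Alternatives were pseudocounts of 0.5 and 5, no filter and a minimum of 50, quantile normalisation, centring on the library median, array weights, robust moderation, a replicate block, the 2 groups alone, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, and leaving out each library in turn. Added after seeing the data were the sum over transcripts of a gene, the transcript of highest median, all transcripts, and the removal of vehicle replicate 3 with anti-PD-1 replicate 1. Tests were tried on simulated counts with 100 genes changed at each of 2 fold sizes. Each comparison used a single simulated table in which genes varied independently. The rates below therefore do not cover structure shared between genes, such as libraries that stand apart. For letrozole against vehicle (19083 genes) limma recovered 50% of 2-fold and 70% of 4-fold changes with 7.41% false calls, edgeR 50% and 69% with 6.87%, and DESeq2 59% and 80% with 18.5%. For anti-PD-1 against vehicle (19088 genes) limma recovered 57% and 72% with 3.65% false calls, edgeR 57% and 74% with 2.19%, and DESeq2 61% and 79% with 13.0%. The work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.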

Results

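RNA was sequenced from 20 mouse mammary tumours, 5 in each of 4 treatment groups, to measure the effects of an aromatase inhibitor and of an antibody against the immune checkpoint receptor PD-1 on transcription. The tumours came from SSM3 cells, an oestrogen receptor-positive mammary tumour line, injected into a mammary gland of 129S6/SvEv mice. Treatment began at a tumour volume of about 150 mm3. The letrozole groups were ovariectomised and given letrozole, which blocks oestrogen synthesis, at 1 mg/kg under the skin each day for 25 days. The other groups had sham surgery and daily 5% ethanol in saline. The anti-PD-1 groups were given 250 µg of antibody on days 3, 5 and 7. The design text calls the 5 tumours of a group biological replicates. Ovariectomy and letrozole always occurred together and cannot be told apart, so "letrozole" below means the surgery and the drug.

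Recovered depth, counted on 1 transcript per gene, ran from 12495788 to 31393828 reads. The median library had 23352002 reads in the vehicle, 16020135 in the anti-PD-1, 25250178 in the letrozole and 26781606 in the letrozole + anti-PD-1 group. At these depths the median tested gene had 262 normalised counts, and the median standard error of a log2 difference between 2 groups was 0.24.

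Tumours of 1 group correlated at r = 0.894 to 0.961 across genes. The first principal component held 20.9% of the variance and the second 13.3%, and 2 libraries stood apart. Vehicle replicate 3 lay at 75.1 on the first component, against −104 to −18.0 for the other vehicle tumours. It also had the highest stromal marker level of its group, with a fibroblast list mean of 10.65 on the log2 scale against 5.23 to 8.60, and an adipocyte list mean of 7.69 against 2.17 to 5.45. Anti-PD-1 replicate 1 lay at −165 on the second component. It had the fewest reads (12495788), the fewest genes detected (20992, against at least 23979 in every other library) and 12.9% of its reads in its 10 most abundant genes, against at most 7.75% in the other libraries. All 20 libraries were kept, and gene counts without these 2 are given with each comparison.

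**Figure D1:**
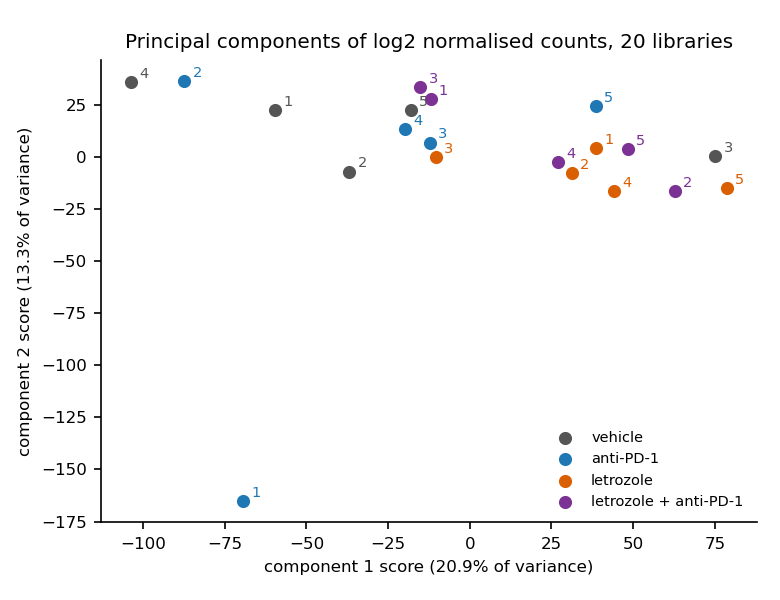
First against second principal component of the log2 values of the tested genes, 1 point per library, coloured by group, with the share of variance on each axis. Vehicle replicate 3 lies at 75.1 on the first component and anti-PD-1 replicate 1 at −165 on the second.

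Letrozole was first compared with vehicle in mice that received no antibody. The progesterone receptor gene Pgr (transcript ENSMUST00000189181), a classical oestrogen receptor target, fell from 15626 ± 2694 to 1370.0 ± 361 normalised counts (mean ± SD, n = 5 per group), 11.6-fold lower (log2 −3.54, SE 0.24, adjusted p = 2.42e-08). The largest change in the comparison's named genes was in Kcne2 (ENSMUST00000047383), a potassium channel subunit, which fell from 4955 ± 1083 to 104 ± 58.1, 50.9-fold lower (adjusted p = 8.59e-07). Stc2 (ENSMUST00000020546), an oestrogen-induced secreted glycoprotein, fell from 7202 ± 2132 to 1008 ± 315, 7.11-fold lower (adjusted p = 1.56e-05), and Il1rl1, the receptor for interleukin-33, from 53159.8 ± 15544 to 8099.9 ± 3911, 7.05-fold lower (adjusted p = 8.92e-04).

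The other genes with the largest falls were F3, which encodes tissue factor (log2 −3.04, SE 0.40), the ephrin receptor gene Epha7 (log2 −3.15, SE 0.37), Coro2b, which encodes an actin-binding coronin (log2 −3.59, SE 0.56), and Hpgd, whose enzyme inactivates prostaglandins (log2 −3.08, SE 0.49). Their adjusted p-values ran from 1.39e-04 to 0.00243. Among genes that rose, Foxj1, a regulator of motile cilia, went from 182 ± 105 to 902 ± 403, 5.10-fold higher (adjusted p = 0.0019), and the kinase gene Hipk2 from 4488 ± 801 to 9480.2 ± 1613, 2.11-fold higher (adjusted p = 2.12e-04). Fam84a rose by 1.74 on the log2 scale, Rcbtb2 by 1.43, the caveolar gene Cavin2 by 1.36, Lysmd3 by 1.29, the oncostatin M receptor gene Osmr by 1.29 and the homeobox gene Irx3 by 1.15 (adjusted p from 5.74e-04 to 0.0087). Lack of overlap between the 5 letrozole and the 5 vehicle values was part of the rule that named these 16 genes. Each of their calls held under all 25 alternatives run. Rcbtb2 shares 13.1% of its exon bases with other genes and Irx3 4.8%, so part of their reads is uncertain. The oestrogen receptor gene Esr1 itself stood at 5482 ± 1101 in vehicle and 6428 ± 571 in letrozole tumours, a log2 difference of 0.25 with a 95% interval of −0.04 to 0.54 (adjusted p = 0.45).

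Of 22 tested genes of the G2/M and mitosis list, all 22 were lower on average with letrozole and 7 fell over all genes tested (22 when adjusted over the list alone), with a median log2 change of −0.73. Cdc20, an activator of the anaphase-promoting complex, fell from 2091 ± 396 to 973 ± 272 (log2 −1.13, SE 0.19, adjusted p = 0.00468), and its call held under all 25 alternatives. Cyclin B1 (Ccnb1, log2 −0.97, adjusted p = 0.0205), the spindle checkpoint kinase gene Bub1b (−0.85, 0.0265) and the mitotic kinesin gene Kif20a (−0.79, 0.0122) also fell. The proliferation marker Mki67 stood at 7905 ± 1636 in vehicle and 4787 ± 1203 in letrozole tumours (log2 −0.73, adjusted p = 0.152) and was not called. The list passed camera with its preset correlation, but its adjusted p = 0.292 with an estimated correlation. Stromal marker levels were also higher on average with letrozole, with wide spread: the fibroblast list mean was 7.99 ± 1.99 in vehicle and 9.31 ± 0.90 in letrozole tumours. With the fibroblast mean as a covariate, the difference of mitotic list means went from −0.76 to −0.65 (95% interval −1.06 to −0.25). Kif20a shares 34.6% of its exon bases with Cdc23, and its level is therefore uncertain.

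Camera called the interferon gamma response list higher with letrozole. Of its 24 tested members 3 rose over all genes (9 when adjusted over the list alone), with a median log2 change of 0.85 and adjusted p = 0.292 with an estimated correlation. Irgm2, an interferon-induced GTPase, rose from 626 ± 137 to 1212 ± 127 (log2 0.97, SE 0.17, adjusted p = 0.00532). The guanylate-binding protein gene Gbp2 rose from 891 ± 251.5 to 1626 ± 309 (adjusted p = 0.0187) and the GTPase gene Igtp from 781 ± 77.9 to 1379 ± 216 (adjusted p = 0.0479). Of 14 tested genes of MHC class I presentation, 2 rose (6 when adjusted over the list alone), with a median of 0.24 and adjusted p = 0.292 with an estimated correlation. These were Tapbp, the peptide-loading chaperone tapasin, from 6478 ± 1673 to 11663 ± 2786 (adjusted p = 0.0252), and the classical class I gene H2-D1, from 41787 ± 3073 to 62506 ± 8516 (adjusted p = 0.0462). Class I genes are near-identical relatives of each other, Tapbp shares 23.5% of its exon bases with another gene and Irgm2 4.7% with Igtp, so these levels are uncertain. Cd274, which encodes the PD-1 ligand PD-L1, stood at 56.9 ± 16.6 in vehicle and 129 ± 20.3 in letrozole tumours (log2 1.21, 95% interval 0.48 to 1.94), a difference that missed the threshold (adjusted p = 0.112). Leukocyte marker means were also higher with letrozole, with wide spread. The macrophage list mean was 8.32 ± 0.98 in vehicle and 9.06 ± 0.32 in letrozole tumours. The T cell list mean was 4.17 ± 1.01 and 4.87 ± 0.91, and limma called 0 members of either list. With these 2 means as covariates the difference of interferon gamma list means went from 0.75 to 0.47 (95% interval 0.07 to 0.87) and that of MHC class I from 0.32 to 0.31.

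**Figure D2:**
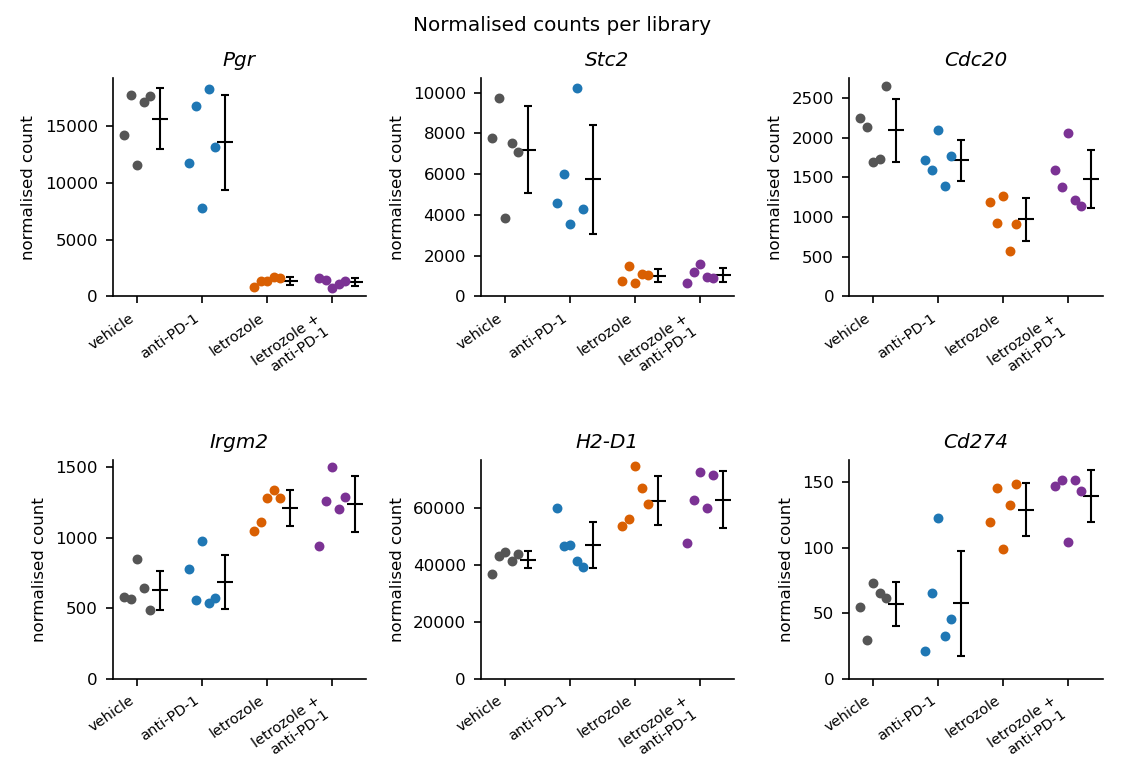
Normalised counts of Pgr, Stc2, Cdc20, Irgm2, H2-D1 and Cd274 in each library, by group, with the mean and SD over 5 tumours. Pgr averages 15626 in vehicle and 1370.0 in letrozole tumours, and Cd274 averages 56.9 and 129.

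Several other lists passed camera downwards in letrozole tumours without single members passing the test over all genes. Ribosomal protein genes had a median of −0.35 over 22 tested members, of which limma called 0 (15 at an unadjusted p under 0.05, 14 adjusted over the list alone, 0 by edgeR and 9 by DESeq2). Cholesterol synthesis genes had a median of −0.39 over 19 members, with 0 called by limma (13 unadjusted, 10 over the list alone, 0 by edgeR, 4 by DESeq2). Mvd averaged 666 ± 215 in vehicle and 383 ± 76.2 in letrozole tumours. Glycolysis genes had a median of −0.42 over 16 members, with 0 called by limma (9 unadjusted, 9 over the list alone, 0 by edgeR, 6 by DESeq2). Ldha, the lactate dehydrogenase gene, averaged 23576 ± 6065 and 15854 ± 1065. Core histone genes had a median of −0.47 over 14 members, with 0 called by limma (7 unadjusted, 7 over the list alone, 0 by edgeR, 4 by DESeq2). The adjusted p was 0.292 for the ribosomal, cholesterol and histone lists and 0.337 for glycolysis with an estimated correlation. Hypoxia genes (median −0.34, adjusted p = 0.337 with an estimated correlation) and S phase genes (median −0.26, adjusted p = 0.298 with an estimated correlation) were also called lower, and in the latter list 1 gene fell, the replication factor gene Rfc4 (log2 −0.55, adjusted p = 0.0446).

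Markers of other cell types were called higher by camera in letrozole tumours, with wide spread between tumours. The basal and myoepithelial list had a median of 2.31 over 10 members (adjusted p = 0.332 with an estimated correlation), of which limma called 0 over all genes (6 unadjusted, 6 over the list alone, 1 by edgeR, 4 by DESeq2). The keratin gene Krt5 averaged 23.6 ± 18.8 in vehicle and 1245 ± 2139 in letrozole tumours. The skeletal muscle list had a median of 2.12 over 15 members (adjusted p = 0.337 with an estimated correlation), of which limma called 0 (8 unadjusted, 1 over the list alone, 0 by edgeR, 3 by DESeq2). Its mean was 7.42, 6.91 and 6.61 in letrozole replicates 1, 4 and 5 and 7.49 in letrozole + anti-PD-1 replicate 2, against 2.30 to 3.87 in the other 16 libraries. Fibroblast (1.41), macrophage (0.83) and complement (0.76) lists were also called higher, with adjusted p = 0.425, 0.378 and 0.378 with an estimated correlation, and the complement gene C1s1 rose from 1320.3 ± 728 to 3266 ± 886 (adjusted p = 0.00722). The T cell list was not called (median 0.55, adjusted p = 0.0777), and neither was the luminal epithelium list (median 0.13, adjusted p = 0.374). In the oestrogen and progesterone response list 3 of 20 members fell, Pgr, Stc2 and Nrip1, a nuclear receptor corepressor (log2 −0.86, adjusted p = 0.0116). That list had 10 members higher and 10 lower, a median of 0.07 and a mean of −0.24, so its median differed in sign from its mean and from camera, which called it lower (adjusted p = 0.358 with an estimated correlation).

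**Figure D3:**
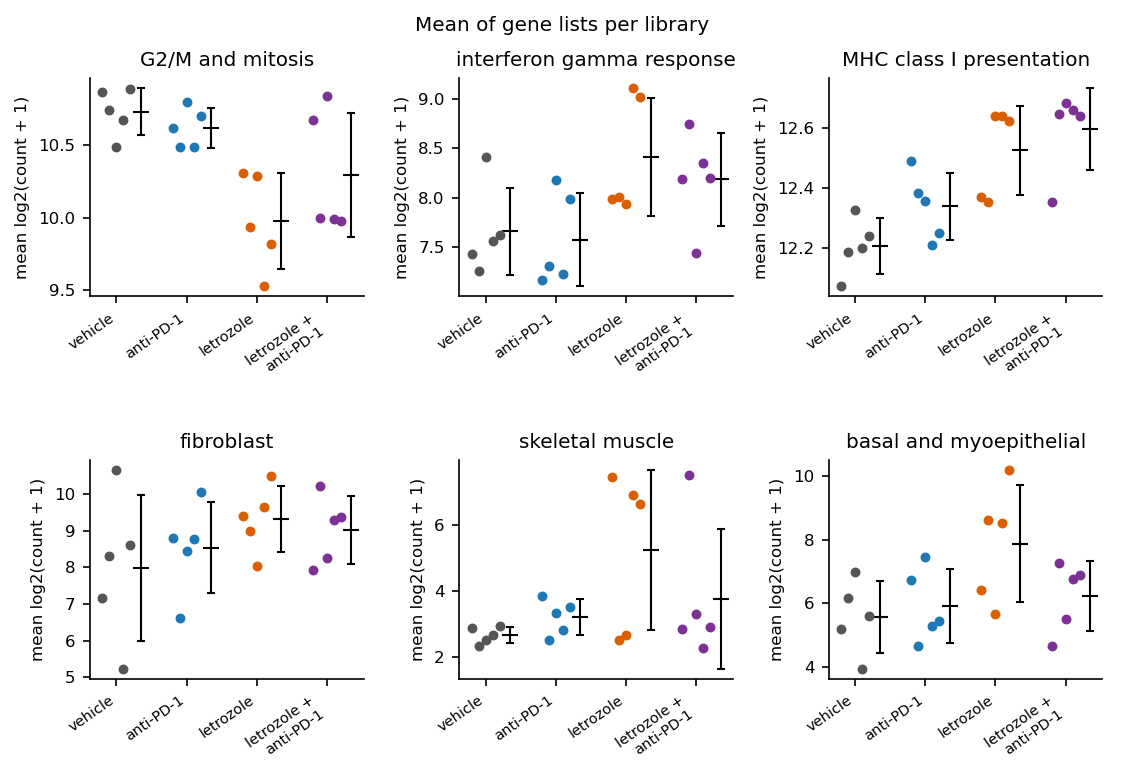
Mean log2(value + 1) over the tested members of 6 gene lists in each library, by group, with the mean and SD over 5 tumours. The G2/M and mitosis list averages 10.73 in vehicle, 10.62 in anti-PD-1, 9.98 in letrozole and 10.30 in letrozole + anti-PD-1 tumours.

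Across 19877 tested genes, 80 rose and 109 fell with letrozole (189 in all; 2751 at an unadjusted p under 0.05, against 994 by chance), and with each library centred on its median 42 rose and 99 fell. edgeR called 169 genes and DESeq2 624. The count was 807 without vehicle replicate 3 (471 rose and 336 fell) and 1140 without both libraries that stand apart, a set chosen after seeing the data (651 rose and 489 fell). Which direction held more calls therefore depended on the libraries kept. It dropped to 86, 90, 117 and 85 without vehicle replicates 1, 2, 4 and 5 and to 91, 103 and 97 without letrozole replicates 3, 4 and 5. Among list members, the call of Kif20a was lost without vehicle replicate 1 (highest adjusted p 0.0505), C1s1 with the 2 groups fitted alone (0.0508) and Ccnb1 without vehicle replicate 1 or 5 or letrozole replicate 4 or 5 (0.0724). Bub1b was lost without vehicle replicate 1, 4 or 5 or letrozole replicate 2, 4 or 5 (0.0954), and Gbp2 (0.0677) and Tapbp (0.0842) without vehicle replicate 1, 2 or 5 or letrozole replicate 3, 4 or 5. Rfc4 (0.127), H2-D1 (0.139) and Igtp (0.139) were lost without any vehicle library but replicate 3 or any letrozole library (for Rfc4, all but replicate 2), among 12 to 14 of 25 alternatives. Camera called 28 of 44 lists, 19 higher and 9 lower, against 0 with an estimated correlation, 3 by fry and 0 by the exact permutation test of list means. In the permutation test 9 lists had an unadjusted p under 0.05. Its smallest p was the lowest possible, 0.00794, but was 0.175 after adjustment, so its count of 0 does not speak against the lists. The oestrogen and progesterone response call was lost without vehicle replicate 3 or letrozole replicate 3 and with quantile normalisation.

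The same treatment was then compared in mice that all received anti-PD-1. Pgr fell from 13533 ± 4150.4 with anti-PD-1 alone to 1235 ± 346 with letrozole + anti-PD-1, 10.9-fold lower (log2 −3.44, SE 0.24, adjusted p = 4.05e-08). Kcne2 fell from 4278 ± 2619.8 to 102 ± 64.6, 46.1-fold lower (adjusted p = 1.36e-06), and Stc2 from 5742 ± 2669 to 1061 ± 353, 5.25-fold lower (adjusted p = 1.02e-04). Il1rl1 fell 8.26-fold, from 46047 ± 8228 to 6618 ± 3450.0 (adjusted p = 3.75e-04). Irx3 rose from 978 ± 339 to 2347 ± 480.0, 2.45-fold higher (adjusted p = 7.14e-04), and Irx3os, the antisense transcript with which it shares 4.8% of its exon bases, from 399 ± 103 to 1087 ± 192, 2.76-fold higher (adjusted p = 3.39e-04).

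Cyp3a57, a cytochrome P450 gene, fell 11.4-fold (adjusted p = 1.02e-04), Hpgd 8.67-fold (0.00183), F3 6.54-fold (0.00116), Epha7 6.52-fold (5.31e-04) and the chemokine gene Cxcl15 6.09-fold (0.0324). Lysmd3 rose 2.27-fold (adjusted p = 0.00133). Foxj1 rose 3.37-fold, the protease inhibitor gene Slpi 7.72-fold and Tll2, which encodes a tolloid-like metalloprotease, 16.2-fold (adjusted p = 0.0204, 0.0287 and 0.0196). The values of Slpi and Tll2 varied widely among the letrozole + anti-PD-1 tumours, at 1194 ± 1055 and 268 ± 312. Esr1 did not differ beyond the replicate spread (log2 0.01, 95% interval −0.28 to 0.31).

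The interferon gamma list was called higher, with 2 of 24 members risen (5 adjusted over the list alone) and a median of 0.59 (adjusted p = 0.626 with an estimated correlation). Irgm2 rose from 684 ± 190 to 1239 ± 200.5 (log2 0.88, adjusted p = 0.0123), and Cd274 from 57.5 ± 40.03 to 139.7 ± 20.03 (log2 1.51, SE 0.35, adjusted p = 0.0405). The Cd274 call was lost under 16 of 25 alternatives (highest adjusted p 0.164), among them the removal of any anti-PD-1 library but replicate 3 and of any letrozole + anti-PD-1 library. Cd274 shares 14.1% of its exon bases with another gene. The macrophage list mean was 8.51 ± 0.76 with anti-PD-1 and 9.03 ± 0.46 with the combination, and with the macrophage and T cell means as covariates the difference of interferon gamma list means went from 0.61 to 0.27 (95% interval −0.12 to 0.66). MHC class I genes had a median of 0.32 (adjusted p = 0.626 with an estimated correlation), with 0 of 14 called by limma (7 unadjusted, 6 adjusted over the list alone, 0 by edgeR, 3 by DESeq2). The G2/M and mitosis list was again called lower (median −0.34, adjusted p = 0.66 with an estimated correlation). All of its 22 members were lower, but limma called 0 of them (4 unadjusted, 0 adjusted over the list alone, 0 by edgeR, 0 by DESeq2). In the hypoxia list (median −0.32) Ddit4, a stress-induced inhibitor of mTOR signalling, fell from 4936 ± 1239 to 2753 ± 246 (adjusted p = 0.00495) and the histone demethylase gene Kdm3a from 6095 ± 543 to 3882 ± 399.7 (adjusted p = 0.00609). In the S phase list (median −0.20) the replication licensing gene Cdt1 fell from 1669 ± 175 to 1079 ± 229 (adjusted p = 0.00898). In the oestrogen and progesterone response list Pgr, Stc2 and Myc fell, the last by 0.85 on the log2 scale (adjusted p = 0.0468), while its median was 0.08 and its mean −0.21, a difference in sign, and camera called it lower. The hypoxia, S phase and oestrogen lists had adjusted p = 0.66 with an estimated correlation. The ribosomal protein list had a median of −0.36 (adjusted p = 0.626 with an estimated correlation), with 0 of 22 called by limma (18 unadjusted, 14 adjusted over the list alone, 0 by edgeR, 3 by DESeq2).

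In this comparison 95 genes rose and 118 fell (213; 2674 at an unadjusted p under 0.05; 233 without both libraries that stand apart). edgeR called 166 and DESeq2 532. Camera called 19 lists, 0 of them with an estimated correlation. The gene count fell to 72 and 123 without anti-PD-1 replicates 4 and 2, to 110, 125 and 117 without letrozole + anti-PD-1 replicates 1, 3 and 5 and to 60 with the 2 groups fitted alone. The list count fell to 12 without letrozole + anti-PD-1 replicate 2, and the call of the oestrogen and progesterone response list was lost without anti-PD-1 replicate 1 or 5 or letrozole + anti-PD-1 replicate 1 (highest adjusted p 0.114). With the 2 groups alone the calls of Ddit4 (highest adjusted p 0.0512), Cdt1 (0.0954), Irgm2 (0.072), Foxj1 (0.07), Slpi (0.0879), Tll2 (0.117), Cxcl15 (0.18) and Myc (0.151) were lost, and that of Epha7 was lost with the sum over transcripts (0.0896). Leaving out anti-PD-1 replicate 4 also ended the calls of Irgm2, Foxj1, Slpi, Cxcl15 and Myc, replicate 5 those of Slpi, Cxcl15 and Myc, replicate 3 that of Slpi, replicate 2 that of Cxcl15 and replicate 1 that of Myc. Leaving out letrozole + anti-PD-1 replicate 3 or 5 ended those of Foxj1, Slpi, Tll2 and Myc, replicate 1 those of Foxj1, Slpi, Cxcl15 and Myc and replicate 2 that of Myc.

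The letrozole effects with and without antibody were measured on separate libraries and could be compared directly. The log2 changes correlated at r = 0.42 across 19877 genes (jackknife SE over libraries 0.18), where genes are not independent replicates. With letrozole labels shuffled within each antibody arm, the highest correlation among the shuffles tried was 0.407. In both comparisons 90 genes were called, all in the same direction. Of these, 38 rose, including Foxj1, Irx3, Lysmd3 and Irgm2, and 52 fell, including Pgr, Kcne2, Stc2, Il1rl1, F3, Epha7 and Hpgd, where independent lists of these sizes would share 0.382 and 0.647 genes. Both comparisons take the variance of a gene from the same fit, so their calls are not fully independent and these expected numbers may be too low. Of the 189 genes called without antibody 188 had the same sign with it, and the changes of the 189 correlated at r = 0.93. Choosing genes by their change in both directions raises such a correlation.

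**Figure D4:**
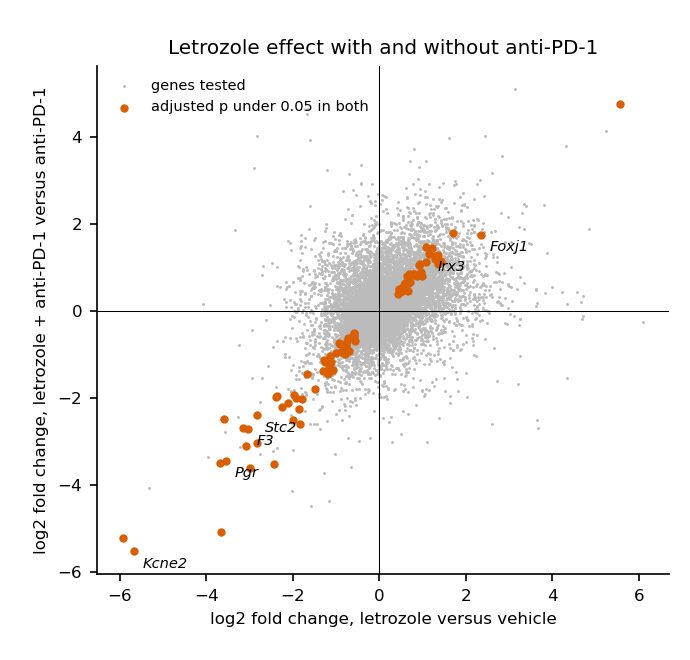
Log2 change with letrozole in mice without antibody (horizontal) against that in mice given anti-PD-1 (vertical), 1 point per tested gene, with genes past the threshold in both in orange (r = 0.419 over all tested genes).

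Averaged over both arms, letrozole tumours had 652 genes higher and 739 lower than the sham-operated groups (1391 called; 4553 at an unadjusted p under 0.05; 1357 by edgeR and 2004 by DESeq2), with a median size of 0.48 on the log2 scale among called genes. In the G2/M and mitosis list 16 of 22 genes fell (22 over the list alone), in the ribosomal protein list 14 of 22 (21 over the list alone), and in the interferon gamma list 9 of 24 rose (16 over the list alone). In the MHC class I list 7 of 14 rose (7 over the list alone). Leukocyte markers moved in the same contrast, with 16 of 18 macrophage genes higher on average and 11 at an unadjusted p under 0.05 in either direction by limma, which called 0 higher and 1 lower. With the macrophage and T cell means as covariates the difference of interferon gamma list means went from 0.68 to 0.37 (95% interval 0.08 to 0.66) and that of MHC class I from 0.29 to 0.27. Each of these 4 lists had adjusted p = 0.28 with an estimated correlation, and passed fry. With each library centred on its median 434 were higher and 698 lower, and with array weights 1369 and 1216. The gene count was 2328 without vehicle replicate 3 (1271 higher and 1057 lower) and 2460 without both libraries that stand apart (1346 and 1114), so the balance of directions depended on the setting.

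Anti-PD-1 alone was compared with vehicle in sham-operated mice. limma called 0 of 19877 genes (541 at an unadjusted p under 0.05, against 994 by chance; 0 by edgeR and 5 by DESeq2), so the genes with the smallest p-values are given as values. Rgs1, a regulator of G protein signalling abundant in activated lymphocytes, stood at 20.2 ± 10.99 in vehicle and 75.2 ± 26.3 in anti-PD-1 tumours (log2 1.95, 95% interval 1.14 to 2.77, unadjusted p = 6.69e-05, limma adjusted p = 1.00), with no overlap between the groups. The protocadherin gene Pcdhb21 stood at 41.9 ± 20.2 and 99.4 ± 32.0, the complement gene C4a at 6.91 ± 6.54 and 21.5 ± 7.35, Ufsp1 at 135 ± 24.7 and 207 ± 22.95 and Hus1b at 6.08 ± 3.42 and 22.0 ± 7.81. In the other direction, Cryl1 stood at 889 ± 727 and 77.7 ± 28.7 (log2 −2.99, but 0.03 with the transcript of highest median), the hypoxia-induced carbonic anhydrase gene Car9 at 13.8 ± 9.19 and 3.28 ± 7.34, Ccdc175 at 12.3 ± 4.77 and 3.09 ± 2.95, Map6d1 at 19.03 ± 6.03 and 5.65 ± 8.98 and Trim62 at 324 ± 24.2 and 228 ± 46.0.

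The PD-1 ligand gene Cd274 and the panel genes Mki67, Foxp3 and Pgr did not differ beyond the replicate spread. The log2 difference was −0.18 for Cd274 (95% interval −0.90 to 0.55), −0.08 for Mki67 (−0.57 to 0.41), 0.15 for the regulatory T cell factor gene Foxp3 (−0.21 to 0.51) and −0.25 for Pgr (−0.75 to 0.25). Pdcd1, which encodes PD-1 itself, averaged 6.18 ± 13.8 in vehicle and 4.65 ± 5.22 in anti-PD-1 tumours, and the T cell genes Cd8a and Cd4 averaged at most 15.2, with a 95% interval for Cd8a from −3.12 to 1.71. At such low counts a change in these genes could not be judged. Camera called 3 lists, MHC class I higher (median 0.15) and cholesterol synthesis (−0.16) and glycolysis (−0.15) lower, each with adjusted p = 0.985 with an estimated correlation. limma, edgeR and DESeq2 each called 0 of their members (1, 1 and 0 at an unadjusted p under 0.05).

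The gene count stayed at 0 by limma without any single library and without both that stand apart. The list count was 20, 1 and 5 without vehicle replicates 3, 1 and 5, 9, 10 and 1 without anti-PD-1 replicates 1, 2 and 5, and 19 without both libraries that stand apart. The MHC class I call was lost without vehicle replicate 1, that of cholesterol synthesis without vehicle replicate 2 or anti-PD-1 replicate 5. The glycolysis call was lost without any of vehicle replicates 1, 2, 4 and 5 and anti-PD-1 replicates 4 and 5.

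Anti-PD-1 was also compared in ovariectomised, letrozole-treated mice. limma called 0 genes (628 at an unadjusted p under 0.05, 0 by edgeR and 9 by DESeq2). It also called 0 without both libraries that stand apart, but these belong to neither group and enter only through the shared variance. Gp5, a platelet glycoprotein gene, stood at 1.22 ± 1.92 with letrozole and 24.2 ± 12.1 with letrozole + anti-PD-1 (log2 3.68, limma adjusted p = 0.913), and Lama3, the laminin α3 gene, at 316 ± 64.7 and 152 ± 48.6 (log2 −1.08, limma adjusted p = 0.703), with no overlap between groups for either. Cdc20 stood at 973 ± 272 and 1478 ± 369, the cell cycle phosphatase gene Cdkn3 at 55.1 ± 20.6 and 103 ± 37.4 and the helicase gene Rtel1 at 667 ± 77.7 and 979 ± 279. Mir8097, which lies wholly inside Rnf19a and so cannot be separated from it, had a log2 difference of 2.69. Lower values with the combination were seen for Fcgbp (382 ± 290.3 and 44.7 ± 76.6), the heat shock gene Hspa1b (287 ± 152 and 114 ± 39.2), Rab18 (3159 ± 241 and 2505 ± 304) and Ggct (93.6 ± 20.9 and 48.0 ± 13.6). Cd274 did not differ beyond the replicate spread (log2 0.12, 95% interval −0.61 to 0.85), nor did Pgr (−0.15, −0.65 to 0.35) or Mki67 (0.43, −0.06 to 0.92).

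Camera called the G2/M and mitosis list higher with the antibody in letrozole-treated mice, with all 22 members higher and a median of 0.32, but its adjusted p = 0.592 with an estimated correlation and limma called 0 members (3 at an unadjusted p under 0.05, 0 by edgeR and by DESeq2). It called 7 lists lower, among them skin and keratinocyte (median −1.28), basal and myoepithelial (−1.14) and mast cell genes (−1.21), with adjusted p = 0.384, 0.592 and 0.627 with an estimated correlation. The G2/M list means were highest in letrozole + anti-PD-1 replicates 1 and 3 (10.67 and 10.84), while replicates 2, 4 and 5 (9.98 to 9.997) stood at the letrozole mean of 9.98. The same 2 tumours had the lowest fibroblast (7.92 and 8.24) and mast cell list means (3.96 and 2.91) of their group, and the mast cell means of the other 3 (6.15 to 7.39) lay near those of letrozole tumours (5.60 to 7.25). The keratin genes Krt14 and Krt1 averaged 1540.0 ± 2101 and 1305 ± 2750.4 in letrozole tumours and 35.2 ± 26.3 and 3.39 ± 2.92 with the combination. The keratin values came mainly from letrozole replicates 4 and 5, where the skin list mean was 8.38 and 10.28.

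The interaction, which asks whether the antibody acts differently with and without letrozole, gave 0 genes by limma and by edgeR (393 at an unadjusted p under 0.05) and 4 by DESeq2. Camera called 7 lists for it, led by G2/M and mitosis (median 0.40), basal and myoepithelial (−2.05) and mast cell (−1.56), each with adjusted p = 0.896 with an estimated correlation. The list count was 18 without vehicle replicate 3, 12 without anti-PD-1 replicate 2 or letrozole + anti-PD-1 replicate 5 and 19 without both libraries that stand apart. Over both arms the antibody gave 0 genes by limma and by edgeR (750 unadjusted) and 1 by DESeq2, Krt1. Camera called 5 lists, of which skin and keratinocyte had a median of −0.93 (adjusted p = 0.452 with an estimated correlation) and was lost with a minimum of 50 (camera adjusted p 0.0711). That list count was 10, 8 and 3 without vehicle replicates 3, 4 and 5, 8 and 2 without anti-PD-1 replicates 1 and 5, 10 and 3 without letrozole replicates 1 and 4, and 9 without letrozole + anti-PD-1 replicate 2. Without both libraries that stand apart it was 15, and the gene counts of the interaction and of the antibody over both arms stayed at 0 by limma. The antibody effects with and without letrozole did not correlate (r = −0.00137, jackknife SE 0.11). DESeq2 called 5 genes for the antibody without letrozole, Adgrb2, Cryl1, Gm18805, Myh2 and Rgs1, and these are named after their values were seen.

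The combination was compared with vehicle last. Pgr fell 12.9-fold to 1235 ± 346 (log2 −3.69, adjusted p = 1.09e-08), Kcne2 60.1-fold (4.06e-07), F3 10.7-fold (6.01e-05) and Cyp3a57 10.3-fold, from 736 ± 75.7 to 82.8 ± 42.2 (9.12e-05). Irx3 rose 3.08-fold (adjusted p = 5.31e-05), Irx3os 2.94-fold and Foxj1 4.34-fold. Adgrv1, a large adhesion G protein-coupled receptor gene, rose from 569.6 ± 281 to 4507 ± 4551 (adjusted p = 0.0141). In the MHC class I list 5 of 14 genes rose (9 over the list alone; adjusted p = 0.235 with an estimated correlation), including Tapbp (log2 0.87), H2-T23 (0.71) and H2-Q4 (0.61), again with the uncertainty of closely related genes. In the interferon gamma list 3 of 24 rose (6 over the list alone; adjusted p = 0.407 with an estimated correlation), Irgm2 (log2 0.99), Igtp (0.94) and Gbp2 (0.85). Leukocyte marker means were also higher with the combination, though limma called 0 members of either list. The macrophage list mean was 8.32 ± 0.98 in vehicle and 9.03 ± 0.46 with the combination, and the dendritic cell one 4.49 ± 1.17 and 5.36 ± 0.83. With the macrophage and T cell means as covariates, a fit added after seeing the data, the difference of interferon gamma list means went from 0.53 to 0.49 (95% interval 0.07 to 0.90) and that of MHC class I from 0.39 to 0.41. Cholesterol synthesis genes were called lower (median −0.50, adjusted p = 0.407 with an estimated correlation), with 2 of 19 fallen (12 over the list alone), among them the lanosterol synthase gene Lss (log2 −0.84), as was glycolysis (median −0.45, adjusted p = 0.424 with an estimated correlation).

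With the combination 91 genes rose and 143 fell against vehicle (234; 2615 unadjusted; 234 by edgeR and 680 by DESeq2), and camera called 21 lists, 0 with an estimated correlation. With each library centred on its median 60 rose and 130 fell. The count was 696 without vehicle replicate 3, 122, 147 and 136 without vehicle replicates 1, 2 and 4, 146, 141 and 141 without letrozole + anti-PD-1 replicates 1, 3 and 5 and 121 with the 2 groups fitted alone, and 954 without both libraries that stand apart. The calls of Tapbp (highest adjusted p 0.0595) and H2-T23 (0.0642) were lost without vehicle replicate 1 or 2 or letrozole + anti-PD-1 replicate 5, that of H2-Q4 without vehicle replicate 1 (0.0685), and those of Igtp (0.0543) and Lss (0.09) without vehicle replicate 2 or letrozole + anti-PD-1 replicate 3 or 5. The call of Gbp2 was lost without vehicle replicate 1, 2 or 5 or letrozole + anti-PD-1 replicate 4 or 5 (0.0702) and that of Adgrv1 with the 2 groups alone (0.0999).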

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

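Among the tests in this part, those of stromal RNA in vehicle replicate 3 and of reads piled on a part of a gene were chosen only after the result was seen. The test of stromal RNA was redefined 2 times before its last form, with slopes taken from the other 19 libraries. The rule that decides the test of a mislabelled tumour was widened after its result was seen, and so was the margin asked of the leukocyte tests. Checks on the lower mitotic genes were also run after their values were seen and are given with the other observations.

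The higher list means of interferon gamma and MHC class I genes with letrozole were weighed against more leukocytes in those tumours, although few members were called and neither list passed with an estimated correlation. With the macrophage and T cell list means as covariates over the 20 libraries, the MHC class I difference between letrozole and vehicle was 0.31 on the log2 scale (SE 0.08, 95% interval 0.13 to 0.48), against 0.32 without them, and 0.23 (0.05 to 0.40) in mice given anti-PD-1. This argues against macrophage and T cell content, as read from these markers, as the whole cause of the class I difference. The T cell list stood at a low level (4.17 in vehicle and 4.87 in letrozole tumours), and an imprecise covariate corrects too little. Dendritic cell (4.49 and 5.47) and plasma cell list means (5.83 and 6.91) were also higher with letrozole and were not in the fit. Other leukocytes are therefore not covered. The interferon gamma difference went from 0.75 to 0.47 (SE 0.19, 0.07 to 0.87), which meets the bound set beforehand against this explanation but by less than its spread, a margin asked for afterwards, and from 0.61 to 0.27 (−0.12 to 0.66) in mice given anti-PD-1, while it went from 0.53 to 0.49 (0.07 to 0.90) for the combination against vehicle and from 0.68 to 0.37 (0.08 to 0.66) over both arms, and since these point different ways leukocyte content stays open for these genes. Abundant leukocyte transcripts (Apoe 2855 ± 2847 in vehicle and 5135 ± 1047 in letrozole, Cd74 3445 ± 5401 and 7599 ± 5772) differed in the same direction, surgery and drug remain confounded, and no biological explanation was tested.

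Vehicle replicate 3 lay among the letrozole libraries on the first component (75.1). Over 213 genes called between the groups given anti-PD-1, which do not include this library, it was nearer to the sham-operated mean in 79.3% of genes, just short of the 80% set beforehand, while the other vehicle libraries reached 87.8% to 96.7% and the letrozole libraries 8.92% to 28.6%. The rule set beforehand is therefore not met, but the gap to the letrozole libraries, a comparison added afterwards, argues against a mislabelled letrozole tumour, and so does the panel gene Pgr, at 11568 in this library against 805 to 1725 in letrozole tumours. Each gene was then adjusted for the fibroblast list mean by setting each library to the mean of its own group. For the vehicle group that mean was taken from the other vehicle libraries. The score of vehicle replicate 3 went to −27.6. The other vehicle libraries then lay at −67.3 to −39.0, the anti-PD-1 ones at −77.8 to −7.76 and the letrozole-treated ones at 8.54 to 42.1. This step uses the group labels and leaves stromal differences between groups in place. The gap to the letrozole-treated libraries is therefore partly set by it. Taken as a vehicle library, it could owe most of its shift from the others to more stromal RNA, as read from fibroblast markers. The adjustment leaves this library within the range of the anti-PD-1 libraries but outside that of its own group. The source of the remainder stays open, adipose markers were not regressed out, and no biological explanation was tested.

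In 74 genes the highest library stood at 1000 or more and at 100 or more times the median plus 1, and in 18 of them that library was anti-PD-1 replicate 1, in 14 letrozole replicate 5 and in 9 anti-PD-1 replicate 2. Examples chosen after their values were seen are the complement gene C3 (median 2369, 257441 in anti-PD-1 replicate 1), Adgrb2 (median 10.3, 103349 in that library) and the stem cell marker Lgr5 (median 19.5, 31378 in that library). Reads piled on a part of the gene would leave other transcripts that share most of its exons nearly empty, and this held for 4 of the 17 genes that could be searched, while 57 had no such transcript. For the 14 genes highest in letrozole replicate 5 it held for 0 of 6 searched, and 13 of the 14 were second highest in letrozole replicate 4. This argues against piled-up reads there, although reads piled on a shared part would escape this test. The skin list mean of these libraries was 10.28 and 8.38, but Krt1 and Krt10 belong both to that list and to the 14 genes, so it is not separate support. For the other genes piled-up reads and true expression in single tumours cannot be told apart, because the bound set for either was not met.

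The values below lay far from the other 4 tumours of their group. They are 28 of 476 groups of 5 examined, close to the share of about 1 in 20 that chance alone gives. Their total is therefore no evidence of unusual tumours, but it does not test how they are spread over libraries. Vehicle replicate 3 and anti-PD-1 replicate 1, the libraries that stand apart, hold 5 each, and letrozole + anti-PD-1 replicate 2 holds 4. Where the other values are all 0, as for Pdcd1, Car9 and Myl1 in vehicle replicate 4, any value above 0 is flagged, and that Myl1 value is 1 read. Anti-PD-1 replicate 5 had 31.4 M recovered reads, against 12.5 to 18.0 M. Anti-PD-1 replicate 1 had 12.9% of reads in its 10 most abundant genes (others 5.96% to 7.75%), 2.76% in transcripts without a gene name (1.92% to 2.08%) and a second component of −165 (6.73 to 36.3). Its Cxcl9 value was 0, against 16.4 to 41.3, and its Cyp3a57 value 275, against 812 to 1224. In vehicle replicate 3 the glycolysis genes Ldha (13149, others 24369 to 28407), Hk2 (756, others 2092 to 2551) and Gpi1 (5845, others 8670.1 to 10172) were low, and the fibroblast gene Pdgfra (1574, others 317 to 437) and Pdcd1 (30.9, others 0) were high. In letrozole + anti-PD-1 replicate 2 the skeletal muscle list mean was 7.49 (2.30 to 3.31), the muscle gene Myl1 74.1 (0 to 1.89), Pdgfra 1367 (708 to 853) and Cd4 71.6 (8.73 to 14.7). In letrozole + anti-PD-1 replicate 3 Cd274 was 104 (143 to 152), Cyp3a57 19.3 (78.8 to 136) and Cxcl15 9.28 (126 to 297), and in replicate 1 of that group the MHC class I list mean was 12.35 (12.64 to 12.68). Anti-PD-1 replicate 3 had Kdm3a at 5167 (6152 to 6574), Adgrv1 at 1911 (563 to 639) and Krt14 at 226 (8.20 to 21.7), and anti-PD-1 replicate 5 had Car9 at 16.4 (others 0). Vehicle replicate 2 had Cyp3a57 at 604 (743 to 784) and Stard4 at 1986 (1066 to 1248), vehicle replicate 1 had Gp5 at 0 (10.7 to 13.6), vehicle replicate 4 had Myl1 at 1.19 (others 0) and letrozole replicate 1 had Adgrv1 at 2557 (1364 to 1579).

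By camera, the letrozole effect differed with and without anti-PD-1 in 7 lists, none of which passed with an estimated correlation. Their median log2 differences were 0.40 for G2/M and mitosis, −2.05 for basal and myoepithelial, −1.56 for mast cell, −1.35 for skeletal muscle, −0.22 for immediate early and heat shock, −0.99 for fibroblast and −0.36 for TGF-beta and matrix genes. Of the 74 genes very high in a few libraries, limma called 0 in the pairwise contrasts and the interaction, and 1 in letrozole over both arms, while DESeq2's antibody calls include some of them (Adgrb2 against vehicle, Krt14, Krt1 and Fam131c between the letrozole groups, Gm37541 and Fam131c in the interaction, Krt1 over both arms). Among 3983 tested transcripts without a gene name, which no comparison of genes uses, 25 were called for letrozole against vehicle, 53 for the combination against vehicle and 24 for the combination against anti-PD-1.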

How the results depend on the processing

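The removal of both libraries that stand apart, the sum over transcripts, the transcript of highest median, the test of all transcripts and the contrasts over both arms were chosen after seeing the data. All other alternatives were planned. A count does not say which genes. Among named genes, 3930 of the results without 1 library kept direction and side of the threshold, 89 gained the call and 181 lost it, and under other settings 5861, 272 and 70. For named lists the counts were 1413 kept and 156 lost without 1 library, 1226 kept and 338 lost under other settings. The endothelial list, letrozole against vehicle, reversed without vehicle replicate 4 (camera lower although the mean log2 difference was 0.0214, adjusted p = 0.893, over all alternatives 0.00104 to 0.893; the highest mean, 0.6246, came without vehicle replicate 3); the cause was not tested. Genes called ranged without 1 library from 85 to 807 for letrozole against vehicle, 122 to 696 for the combination against vehicle, 72 to 255 against anti-PD-1 and 932 to 2328 for letrozole over both arms, and stayed at 0 for the 3 antibody contrasts and the interaction. Lists called ranged from 22 to 30, 1 to 20 (anti-PD-1 against vehicle), 17 to 24, 6 to 12 (the combination against letrozole), 12 to 21, 5 to 18 (interaction), 22 to 28 (letrozole over both arms) and 2 to 10 (anti-PD-1 over both arms). The correlation between arms ranged from 0.306 to 0.470 for letrozole and from −0.0594 to 0.0539 for anti-PD-1. With no filter, and so more genes tested, the combination against anti-PD-1 gave 110 genes. With a minimum of 50, lists called were 5 for anti-PD-1 against vehicle, 4 for the combination against letrozole and 3 for anti-PD-1 over both arms. Array weights, which gave vehicle replicate 3 a weight of 0.592 and anti-PD-1 replicate 1 of 0.268, called 733 genes for letrozole, 560 for the combination against vehicle and 2585 for letrozole over both arms. Fits of the 2 groups alone, with fewer samples, called 121 and 60 for the combination against vehicle and against anti-PD-1. DESeq2 called 624, 5, 680, 9 and 532 genes in letrozole against vehicle, anti-PD-1 against vehicle, the combination against vehicle, against letrozole and against anti-PD-1, 4 for the interaction and 1 for anti-PD-1 over both arms. Its false share in simulation was higher than that of limma, but the simulated genes varied independently, unlike those of these libraries. Without both libraries that stand apart the counts were 1140 for letrozole, 954 for the combination against vehicle and 2460 for letrozole over both arms, and lists called were 19 for anti-PD-1 against vehicle, 19 for the interaction and 15 for anti-PD-1 over both arms; the cause was not tested. With an estimated correlation camera called 0 lists in each of the 8 contrasts, where smallest adjusted p-values ran from 0.235 to 0.985. Fry, which asks another question, called 3 for letrozole, 1 for the combination against vehicle, 10 for letrozole over both arms and 0 elsewhere, and the exact permutation test of list means 0 in the 5 pairwise contrasts, except that without vehicle replicate 3 it called 15 for letrozole (range without 1 library 0 to 15). The replicate numbers do not pair the tumours: same-numbered tumours correlated from −0.343 to 0.196 over 30 pairs and 1 of 20 correlated best with its own number. With the replicate block the counts were 221, 0, 280, 1 and 236 for the pairwise contrasts in the order above and 0, 1393 and 0 for the interaction and the contrasts over both arms. Summed transcripts gave 162, 0, 232, 0 and 184. At these depths Cd8a, Cd4, Pdcd1 and Cxcl9 had few reads, and Gzmb, Prf1, Ifng and Cyp19a1 were below the filter.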

Other observations

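All gene and list names in this part that the naming rule does not give were chosen after their values were seen, and so were the tests over both arms and the checks on mitotic genes against luminal ones. The other counts of splits were planned.

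Other lists fixed before the data were examined were called by camera in letrozole against vehicle tumours. Milk protein and lactation genes had a median log2 difference of 1.22 over 7 members, and Mfge8, which encodes a milk fat globule protein, stood at 2402 ± 697 in vehicle and 5038 ± 686 in letrozole tumours (adjusted p = 0.0552), with no overlap between groups. MHC class II (1.23), tertiary lymphoid structure (1.55), dendritic cell (0.85), T cell checkpoint (0.77) and type I interferon genes (0.50) were called higher, with Xaf1 at 541 ± 164 and 1086 ± 351 and Oasl2 at 227 ± 96.1 and 573 ± 167. TGF-beta and matrix (0.79), adipocyte (1.44), Wnt target (0.70), p53 target (0.34), TNF (0.37) and endothelial genes (0.33) were also called higher and unfolded protein response genes lower (−0.19). The adjusted p of these lists ran from 0.332 to 0.57 with an estimated correlation, and the calls of the adipocyte, endothelial, TGF-beta, Wnt, dendritic cell and T cell checkpoint lists were lost without vehicle replicate 4.

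The luminal epithelium list gave a reference for the mitotic genes. In letrozole against vehicle the 95% intervals of 13 of its 16 members lay above the mitotic list's median of −0.73, and in mice given anti-PD-1 those of 10 of 16 lay above its median of −0.34. With the fibroblast list mean as a covariate the mitotic list mean differed by −0.65 (−1.06 to −0.25) against −0.76 without it, and in mice given anti-PD-1 by −0.29 (−0.67 to 0.09) against −0.33. A lower share of tumour cells would lower luminal and mitotic genes alike. The luminal list mean was 13.50 in vehicle and 13.40 in letrozole tumours. Against vehicle these values argue against a lower share as the whole cause of the mitotic difference, as far as luminal genes track tumour cells. That is uncertain, since over both arms limma called 3 of the 16 luminal members higher and 2 lower. In mice given anti-PD-1 the luminal list mean was 13.50 without and 13.32 with letrozole, and the interval of the mitotic difference includes 0. Whether a lower share of tumour cells explains it stays undecided there.

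Of limma, edgeR and DESeq2 fitted on group means, only DESeq2 called genes for the antibody. With the replicate block limma called 1 between the letrozole groups. Of its 5 calls against vehicle, Adgrb2 stood at 103349 in anti-PD-1 replicate 1 and 38553.9 in replicate 3, Gm18805 at 7857 in replicate 3, and Myh2 at 0 in every vehicle library and 2.76 ± 4.78 in anti-PD-1 tumours. Cryl1 stood at 889 ± 727 in vehicle and 77.7 ± 28.7 in anti-PD-1 tumours, and Rgs1 at 20.2 ± 10.99 and 75.2 ± 26.3. Of its 9 calls between the letrozole groups, Krt14, Krt1, Krt6b, Krt17 and Krt16 were highest in letrozole replicates 4 and 5, and the others were Lama3, Gp5, Fam131c and Gm47132. Its 4 interaction calls were Serpina9, Gm37541, Fam131c and Gm9866.

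Counts of calls were compared with those from 100 splits of the same libraries, the real one included. For genes, 2 splits gave as many as the 189 of letrozole against vehicle (highest other 755) and 2 as many as the 234 of the combination against vehicle (373). In both, another split gave more calls than the real one, so chance is unlikely there but cannot be excluded. For the 213 of the combination against anti-PD-1 (5) and the 1391 of letrozole over both arms (1) only the real split gave as many. This is the smallest share that 100 splits can show. The split with 755 calls exchanges vehicle replicate 3 with letrozole replicate 3, and that with 373 exchanges it with letrozole + anti-PD-1 replicate 3, which points to a structure of the samples around that vehicle library. For anti-PD-1 against vehicle the real count was 0, which every split must reach, so the comparison says nothing about chance there. The highest other split gave 138, with vehicle replicates 1, 2 and 4 and anti-PD-1 replicates 1 and 2 in 1 group, again a structure of the samples. The real counts of the combination against letrozole, the interaction and anti-PD-1 over both arms were also 0, so the same limit holds. Their highest others were 2, 1 and 3.

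For lists called by camera, chance cannot be excluded in any contrast. As many lists as the real count were called by 9 of 100 splits for letrozole against vehicle (real 28, highest other 33), 94 for anti-PD-1 against vehicle (3, 27), 30 for the combination against vehicle (21, 31), 67 for it against letrozole (8, 30), 14 for it against anti-PD-1 (19, 24), 81 for the interaction (7, 29), 7 for letrozole over both arms (27, 29) and 94 for anti-PD-1 over both arms (5, 29). The correlation of the letrozole effects between arms (0.419, jackknife SE 0.18) was reached by 1 split, the real one. The highest other was 0.407, and the gap is far smaller than that SE, so chance is unlikely but cannot be excluded. That of the antibody effects (−0.00137) was reached by 53 (highest other 0.269).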
